A study of Canis lupus familiaris with 4 samples.

How the data were processed

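RNA was measured in stem-like cells of 2 canine mammary cancer lines, P114 and CMT-U27, at day 3, after co-culture with tumour-associated macrophages or after single culture. Per the labels, each of 4 arrays held both cultures of a line in different dyes, and the dyes were exchanged between the 2 arrays of each line. In P114 replicate 1 and CMT-U27 replicate 2 the co-culture was in Cy3, and in P114 replicate 2 and CMT-U27 replicate 1 it was in Cy5. Dyes were taken from the label of each channel. The title of each record names the culture of its channel 1 alone, and channel 1 is Cy3 in both P114 records and Cy5 in both CMT-U27 records. If that order were an error in the records of a line, all ratios of that line would change sign. The arrays are numbered in the order of their records, and the numbers pair nothing across lines. The labels call the arrays biological replicates without saying whether the dye-swapped arrays held separate RNA extracts, so the spread between them may be technical. All 4 arrays lay on 1 slide, so no slide effect could be tested.

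The deposited scanner files hold linear intensity values per spot, with the local background, as written by Agilent Feature Extraction; the file headers name version 10.10.1.1 and the submitters' processing notes name version 10.7.3.1. Per the file headers, the log10 ratio column is red (Cy5) over green (Cy3) after the software's own background subtraction and dye normalization. The authors' series value table was the same log10 ratio for all 45220 spots of each array, with a largest gap of 0, a median of 0 in each column and no turning for the dye swap, so scale, centring and direction were all known. It was used as an alternative only. The array design is 021193 per the file headers, which place probes on the canine assembly CanFam3.1. The deposited flags of 0 or 1 per spot were used for filters.

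Each array held 45220 spots, of which 1417 were controls. Mean spot intensities were corrected with normexp against the median local background with an offset of 50, and loess was applied within each array with control spots at weight 0. Spots marked as non-uniform or as population outliers in either channel were left out, spots of the same probe were averaged, and each log2 ratio was turned to co-culture over single culture. Of 43603 probes, 22344 had a gene symbol in the files (13739 symbols), and 12666 of these symbols were found in the RefSeq table of assembly UU_Cfam_GSD_1.0, which was used for names only. Probes were kept when well above background on both arrays of at least 1 of the line and culture combinations, which left 28692 probes, 17722 of them with a symbol, for 10775 genes. A further 40 probes were lost to a marked spot on an array. A gene with several tested probes, as 4452 genes had, was shown by its brightest probe. Precision was limited by the number of arrays.

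Tests were made with limma 3.58.1 in R 4.3.3, with version 1.17.8 of data.table. The log2 ratios of all 4 arrays were fitted with a coefficient per line and a probe-specific dye term, which left 1 residual degree of freedom beside 2.76 prior degrees of freedom. Comparisons were P114, CMT-U27, the mean of both lines and CMT-U27 minus P114, at a Benjamini-Hochberg adjusted p under 0.05. The 17 gene lists, with 444 distinct genes of which 413 were on the array and 346 were tested, were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 17 lists within each comparison. At this preset camera sets the members' statistics against the spread over genes, so its p-values do not measure the spread between arrays. With an estimated correlation it has 1 residual degree of freedom, and the smallest unadjusted p of any list was 0.0802. The lines themselves were compared in single culture by a separate-channel fit after loess and Aquantile normalization. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

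Designs, gene lists and most alternatives were set before the data were examined. Genes were named by a rule set at that time. Among probes past the threshold with the same sign on the arrays, the 10 largest in each direction were to be named. Where fewer than 5 passed, the 5 largest mean log2 ratios were named as values, if the unadjusted p was under 0.05, the sign was the same and the arrays lay less than 1 log2 unit apart. Up to 4 members of each list with the smallest unadjusted p were added, and always EPCAM, CD44, CD14, CSF1R, CD163, VEGFA, IL8 and MKI67. For the difference between lines the same sign was required within each line's 2 arrays. For the mean and the difference the distance between arrays was taken within each line, so arrays of different lines could lie further apart.

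Alternatives were no background correction, the scanner software's own log ratio, the series value table, median centring in place of loess, Aquantile after loess, no filter on dim probes, a filter on all channels, marked spots kept, no dye term, each array left out in turn, the 2 arrays of each line averaged first, an estimated inter-gene correlation and the mean over all probes of a gene. The line comparison was repeated with quantile normalization of all channels. Chosen after seeing the data were leaving out spots marked for their local background, fitting a line's own arrays alone and turning P114 replicate 1 or 2 against its label. Fits that left out an array had no dye term, since with it no residual degree of freedom was left. Fits with a P114 array turned kept the dye term. Both P114 arrays then had the same sign, so the dye term came from the CMT-U27 arrays alone and the residual from the P114 arrays alone.

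The fit was tested on simulated data for CMT-U27 with 28692 probes. It recovered 0 of 50 probes at an absolute log2 ratio of 0.5, 32 of 50 at 1, 47 of 50 at 2 and 50 of 50 at 3, with 10 false calls. With each probe's own moderated spread in the simulation it recovered 46 of 50 at 0.5 and 50 of 50 at 1, with 59 false calls and 21 more in the unchanged P114 comparison. Changed probes of all sizes were simulated together, which eases the adjusted threshold for each of them. Recovery may thus be too high for data with fewer changed probes. In the data SAA1, at a log2 ratio of 3.23 in CMT-U27, was not called. A simulated list shift of 0.15 log2 over 10775 genes was found in 20 of 20 rounds, with 0 false calls among 320 unshifted lists. The simulated genes were independent of each other. In the data the correlation between members was estimated from 1 residual degree of freedom per gene, and is thus uncertain. That residual is the gap between the lines in the dye term, not a spread between replicates within a line. The estimated correlation was 0.26 for inflammatory targets, 0.264 for antigen presentation and 0.382 for epithelial markers. The simulation therefore cannot show how often lists of correlated genes are called falsely. The separate-channel fit, simulated with 6000 probes, recovered 87 of 100 probes at a log2 difference of 1 and 100 of 100 at 2. All these probes shared the same spread, unlike the real ones, so the recovery may be too high. The correlation between the channels of a spot was estimated at 0.941 where 0.664 had been simulated, and at 0.937 in the data.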

Results

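Gene expression was measured on 2-colour arrays in stem-like cells of P114 and CMT-U27, cell lines derived from canine mammary cancer. The cells had been sorted for Sca1, EpCAM and CD44, surface proteins used to enrich stem-like cells, and were kept for 3 days with tumour-associated macrophages or alone. Each line had 2 arrays with exchanged dyes, and every ratio is given as co-culture over single culture. The share of spots well above background was 89.4% in Cy3 and 91.7% in Cy5 on P114 replicate 1, and lay between 57.9% and 65.7% in both channels of the other 3 arrays. No spot was saturated (0 on each array). Before loess normalization the co-culture channel was brighter at bright spots on 3 arrays, with a median log2 ratio in the brightest of 5 equal groups of spots of 0.84 on P114 replicate 1, 1.34 on CMT-U27 replicate 1 and a higher value on CMT-U27 replicate 2, against 0.01 on P114 replicate 2. Loess removes such a trend, so all changes are relative to other genes of the same brightness. With median centring in its place, the median over all tested probes moved to 0.16 in P114 and 0.68 in CMT-U27.

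In CMT-U27 cells, the 5 largest positive ratios by the naming rule were those of SAA1, PI3 and the chemokine genes CCL2, CCL4 and CCL20, and none passed the test over all probes. SAA1, which encodes the acute-phase protein serum amyloid A, had a mean log2 ratio of 3.23 ± 0.17 (SD, n = 2 arrays), or 9.36-fold. Its probe lies on chromosome 21 from 40629375 to 40629434 of CanFam3.1. PI3, which encodes the elastase inhibitor elafin, stood at 1.79 ± 0.02, or 3.45-fold. CCL2, CCL4 and CCL20 stood at 1.62 ± 0.14, 1.46 ± 0.19 and 1.45 ± 0.26. By their other probes CCL2 stood at 0.17 ± 0.07 and PI3 at 0.56 ± 0.02. The 5 SAA1 probes were all above 0, from 0.22 to 3.23. The largest negative ratios were smaller, with COL12A1, a fibril-associated collagen gene, at -0.51 ± 0.04, PCP4 at -0.40 ± 0.20 and CDO1, a cysteine-degrading enzyme gene, at -0.37 ± 0.13. INPP5K (-0.44 ± 0.58) and IVD (-0.41 ± 0.56) were negative at their brightest probes, with a spread between the arrays larger than their mean. The other IVD probes stood at 0.13 ± 0.05 and 0.20 ± 0.07, and the other INPP5K probes between -0.06 and 0.11.

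Inflammatory NF-kB targets rose as a group in CMT-U27. Of 30 measured genes, 26 were higher and 4 lower, with a median log2 ratio of 0.26 (camera adjusted p = 5.15e-16, and adjusted p = 0.94 with an estimated correlation). Counted as adjusted over the list alone, 13 of them were higher and 0 lower, while 0 passed over all probes. Here and below, the camera p with an estimated correlation rests on 1 residual degree of freedom, and the other on the spread over genes. The gap between them is thus not a measure of correlation between members. Besides the chemokines above, CCL8 stood at 1.17 ± 0.16, CXCL10 at 0.71 ± 0.20 (positive by 2 of its 3 probes) and NFKBIA, the inhibitor that NF-kB itself induces, at 0.63 ± 0.08. The 13 measured macrophage markers had a median of 0.01 (adjusted p = 0.856), with CD14 at 0.04 ± 0.03 and CD68 at 0.13 ± 0.05. The markers C1QC, FCER1G and SPI1, looked up after their values were seen, were well above background in the co-culture channel of 1 of 2 CMT-U27 arrays and in the single-culture channel of 0 of 2. With median centring in place of loess the inflammatory list had an adjusted p of 0.0542.

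Antigen presentation genes also rose as a group in CMT-U27, with 20 of 22 higher and a median log2 ratio of 0.30 (adjusted p = 2.25e-11, and adjusted p = 0.94 with an estimated correlation). Adjusted over the list alone, 11 were higher and 0 lower. DLA-DRB1, a class II molecule, stood at 0.60 ± 0.11, CIITA, the class II transactivator, at 0.46 ± 0.02 and the immunoproteasome gene PSMB9 at 0.44 ± 0.02. The lowest probes of DLA-DRB1 and CIITA stood at 0.10 ± 0.08 and 0.06 ± 0.04. With median centring the adjusted p of this list was 0.397. Cholesterol synthesis genes rose by less, with 21 of 22 higher and a median of 0.16 (adjusted p = 4.07e-07, and adjusted p = 0.94 with an estimated correlation). Adjusted over the list alone, 0 of them passed. HMGCS1, the synthase at the head of the pathway, stood at 0.36 ± 0.16, SQLE, squalene epoxidase, at 0.31 ± 0.05 and INSIG1, a sterol-regulated inhibitor, at 0.30 ± 0.03.

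The other lists did not pass in CMT-U27. Epithelial markers had a median of 0.15 (adjusted p = 0.189) with KRT15 at 0.81 ± 0.14 and KRT18 at -0.32 ± 0.29, and cell cycle genes a median of 0.07 (adjusted p = 0.189). Interferon response genes had a median of 0.05 and unfolded protein and stress response genes of 0.02 (both adjusted p = 0.179). Extracellular matrix and protease genes had a median of 0.03 and angiogenesis genes of 0.01 (both adjusted p = 0.298), with FN1, the fibronectin gene, at 0.54 ± 0.13. The other FN1 probes lay between 0.002 and 0.425. Medians were 0.05 for hypoxia and glycolysis, 0.04 for the Wnt pathway and 0.00 for endothelial markers (all adjusted p = 0.856). They were 0.07 for stem-like cell and sort markers and 0.04 for epithelial-mesenchymal transition (both adjusted p = 0.955). Fibroblast and stromal markers had a median of 0.01 (adjusted p = 0.484) and lymphocyte markers of -0.01 (adjusted p = 0.199). Adjusted over the list alone, 1 epithelial marker, 1 interferon response gene and 1 gene of epithelial-mesenchymal transition were higher.

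Over single genes, limma called 0 of 28692 probes in CMT-U27 after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.147, for SAA1. At an unadjusted p under 0.05 there were 928 probes, 663 higher and 265 lower, against 1435 that chance would give. Without background correction 12 probes passed, all of them higher, and these included SAA1, PI3, CCL4, CCL20 and CXCL10. With median centring in place of loess 17343 passed, 17025 of them higher. Without CMT-U27 replicate 1, in a fit with no dye term, 17 passed, 2 of them higher and 15 lower. With either P114 array turned against its label 27 passed, 9 of them higher and 18 lower. The CMT-U27 ratios themselves stayed the same in those fits, and only the residual spread changed, which then came from the P114 arrays.

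**Figure D1:**
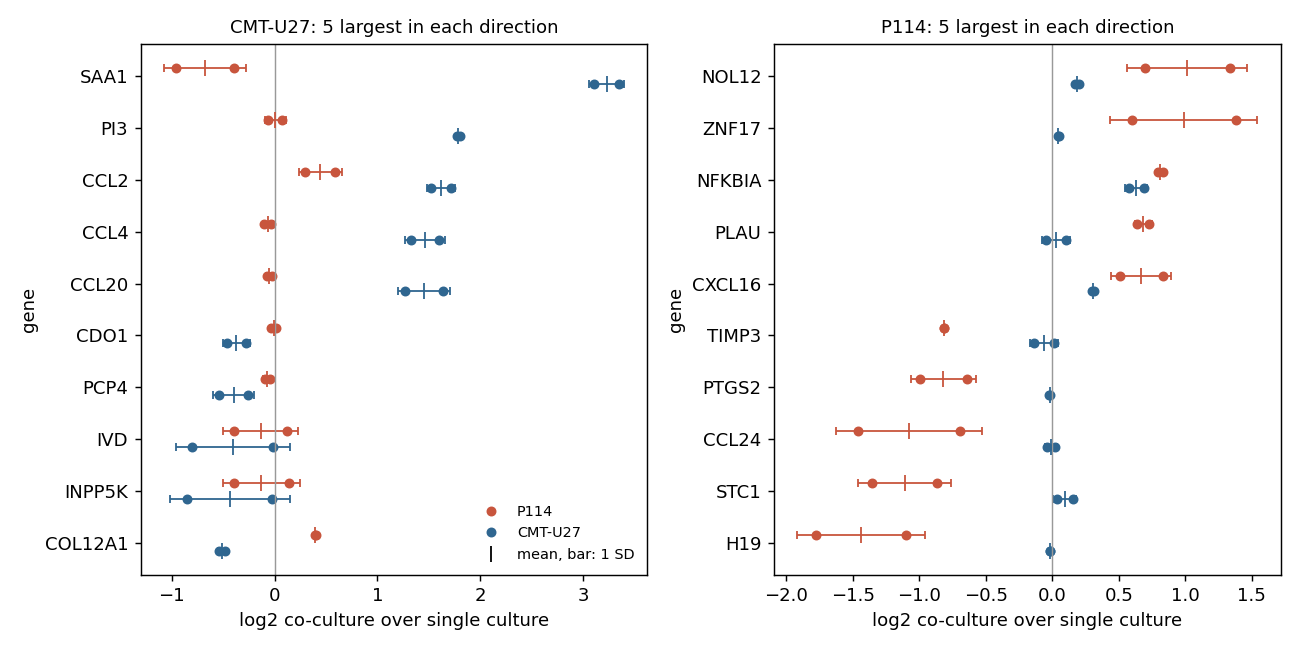
Log2 ratio of co-culture over single culture (horizontal axis) for the 5 genes with the largest positive and negative mean ratios in CMT-U27 (left) and P114 (right) by the naming rule. Points are the 2 arrays of each line, the vertical mark is their mean and the bar is 1 SD; SAA1 stood at 3.35 on the higher of the CMT-U27 arrays and at -0.40 and -0.96 on the P114 arrays.

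In P114 cells other genes had the largest ratios. H19, a non-coding RNA of an imprinted locus, had a mean log2 ratio of -1.44 ± 0.48 (SD, n = 2 arrays), or 2.71-fold lower, with its probe on chromosome 18 from 46204929 to 46204988 of CanFam3.1. STC1, the gene of the secreted glycoprotein stanniocalcin, stood at -1.11 ± 0.35, CCL24 at -1.08 ± 0.55 and PTGS2, which encodes cyclooxygenase-2, at -0.82 ± 0.25. TIMP3, a metalloproteinase inhibitor gene, was at -0.81 on both arrays by 1 of its 4 probes and at -0.53 ± 0.05 by its brightest. On the positive side stood NOL12 at 1.02 ± 0.45 (0.12 ± 0.00 by its other probe), ZNF17 at 0.99 ± 0.55, NFKBIA at 0.81 ± 0.03, PLAU, the urokinase gene, at 0.69 ± 0.06 and CXCL16 at 0.67 ± 0.23. These directions rest on the labelled dyes, as those in CMT-U27 do, and the records list Cy3 first in P114 and Cy5 first in CMT-U27. The P114 genes were named for the same sign on both arrays as labelled. If the label of a P114 array were wrong, their 2 ratios would oppose each other and their rank would not hold. The 2 P114 arrays disagreed, since over all probes the 2 P114 arrays correlated at -0.149 (Pearson, across probes, which are not independent replicates) and the CMT-U27 arrays at 0.053. By Spearman's rho these values were -0.2 and -0.008. Of the probes beyond 0.3 in absolute log2 ratio on both P114 arrays, 88 were higher on both, 82 lower on both and 561 opposite.

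Cell cycle genes rose as a group in P114. Of 32 measured, 30 were higher, with a median log2 ratio of 0.20 (adjusted p = 4.54e-12, and adjusted p = 0.811 with an estimated correlation), and 1 was higher adjusted over the list alone. MCM2, a subunit of the replicative helicase, stood at 0.53 ± 0.28, CENPF, a kinetochore protein gene, at 0.33 ± 0.07 and CDC20, an activator of mitotic exit, at 0.32 ± 0.18. MKI67, a proliferation marker, stood at -0.01 ± 0.14. With P114 replicate 1 turned against its label the list pointed down and with replicate 2 turned it pointed up, both at an adjusted p of 0.91. Both alternatives were chosen after seeing the data.

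Cholesterol synthesis genes fell as a group in P114, with 19 of 22 lower and a median of -0.13 (adjusted p = 4.44e-06, and adjusted p = 0.811 with an estimated correlation). Adjusted over the list alone, 0 passed. INSIG1 stood at -0.45 on both arrays, FDFT1, squalene synthase, at -0.30 ± 0.10 and HMGCS1 at -0.39 ± 0.38. Their other probes gave smaller falls, at -0.22 and -0.09 for INSIG1, -0.205 for FDFT1 and -0.12 and -0.16 for HMGCS1. With either P114 array turned the adjusted p was 0.91, and with median centring it was 0.348. Stem-like cell and sort markers fell as a group (10 of 15 lower, median -0.08, adjusted p = 0.0166, and adjusted p = 0.811 with an estimated correlation), with PROM1 at -0.55 ± 0.07 and MYC at -0.46 ± 0.20, and 1 was lower adjusted over the list alone. Epithelial markers fell as a group (12 of 17 lower, median -0.06, adjusted p = 0.0238, and adjusted p = 0.811 with an estimated correlation), with the basal keratin gene KRT5 at -0.53 ± 0.38 and KRT18 at -0.26 ± 0.10, and 0 passed adjusted over the list alone. With P114 replicate 1 turned the stem-like and epithelial lists stood at 0.885 and 0.426, and with replicate 2 turned they pointed up at the same values. Their calls also ended with the scanner software's own log ratio (0.0971 and 0.173), no filter on dim probes (both 0.0554) and median centring (0.161 and 0.376). In fits with no dye term the stem-like list lost the call without P114 replicate 1 (0.0764) and without P114 replicate 2 (0.373), as did the epithelial list (0.169 and 0.343).

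The inflammatory list had 15 genes higher and 15 lower in P114 (adjusted p = 0.966), although adjusted over the list alone 1 was higher and 2 were lower. SAA1 stood at -0.68 ± 0.40 (negative by 3 of its 5 probes) and CCL2 at 0.45 ± 0.21 (0.07 ± 0.15 by its other probe). Wnt genes had a median of 0.05 (adjusted p = 0.375), with WNT7A at 0.54 ± 0.16. The 29 angiogenesis genes had a median of 0.02 (adjusted p = 0.577), and 2 were higher adjusted over the list alone. PLAUR, the urokinase receptor gene, stood at 0.46 ± 0.01 and ANGPTL4 at 0.35 ± 0.02. Macrophage markers had a median of 0.00 (adjusted p = 0.577), with CD86, a co-stimulatory molecule gene, at -0.35 on both arrays.

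In P114 limma called 0 of 28692 probes, with a smallest adjusted p of 0.797. At an unadjusted p under 0.05 there were 1758 probes, 1086 higher and 672 lower, against 1435 by chance. With median centring 5 probes passed, those of GRAP (looked up after its value was seen), NOL12, ZNF17, NFKBIA and 1 without a gene symbol. In fits with no dye term, 64 passed without P114 replicate 2 and 0 without P114 replicate 1. With P114 replicate 1 turned against its label 14 passed, 1 of them higher and 13 lower, and with replicate 2 turned 14 passed, 13 higher and 1 lower. Those fits took the dye term from the CMT-U27 arrays alone, and it became part of the P114 value. All genes of these 14 probes were also called in CMT-U27 by the same fits. The 14 calls therefore cannot be read as P114 effects that a wrong label had hidden.

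Averaged over both lines, NFKBIA (mean log2 0.72), CCL2 (1.03), CXCL16 (0.49), NOL12 (0.60) and ZNF17 (0.52) had the largest positive ratios with the same sign on all 4 arrays. The other probes of CCL2 and NOL12 gave smaller ratios in both lines. H19 (-0.73), TIMP3 (-0.31 at its brightest probe), PTGS2 (-0.42), FOS (-0.42) and AMN (-0.31) were negative on average. In CMT-U27 alone H19 stood at -0.01, PTGS2 at -0.02, NOL12 at 0.19 and ZNF17 at 0.05. H19 and PTGS2 were well above background there on 1 of 2 arrays, and ZNF17 on 0 of 2 in single culture. As groups, cell cycle genes rose (31 of 32 higher, median 0.13, adjusted p = 2.23e-08), as did antigen presentation genes (21 of 22, median 0.18, adjusted p = 9.33e-08), inflammatory NF-kB targets (24 of 30, median 0.14, adjusted p = 2.54e-07) and extracellular matrix and protease genes (26 of 34, median 0.08, adjusted p = 0.0484). All 4 had an adjusted p = 0.808 with an estimated correlation. The cell cycle list pointed down with P114 replicate 1 turned (camera adjusted p = 0.974) and lost its call with replicate 2 turned (0.716). With median centring, antigen presentation (0.722) and inflammatory targets (0.385) lost theirs. The matrix and protease list passed in 5 of 18 settings and lost its call with no dye term (0.0621). Adjusted over the list alone, 8 antigen presentation genes were higher, as were 11 inflammatory genes with 1 lower, 3 matrix and protease genes with 1 lower, and 0 cell cycle genes. PLAT, the tissue plasminogen activator gene, stood at 0.27 ± 0.13 in P114 and 0.34 ± 0.00 in CMT-U27. Over all probes limma called 0, with 1881 at an unadjusted p under 0.05 (1441 higher, 440 lower) and a smallest adjusted p of 0.714. In fits with no dye term, which gave 0 calls over all arrays, there were 61 calls without P114 replicate 2 and 8 without CMT-U27 replicate 1. With P114 replicate 1 turned there were 20, with replicate 2 turned 0, and with median centring 16518.

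The response to co-culture differed between the lines for 6 lists, as CMT-U27 minus P114. Cholesterol synthesis genes had a higher ratio in CMT-U27 in 22 of 22 cases (median difference 0.25, adjusted p = 2.16e-11, and adjusted p = 0.824 with an estimated correlation), and 5 passed adjusted over the list alone. INSIG1 differed by 0.75, HMGCS1 by 0.74 and FDFT1 by 0.58 at the probes shown, and their other probes had smaller negative ratios in P114. Inflammatory NF-kB targets were higher in 23 of 30 (median 0.23, adjusted p = 3.35e-10, and adjusted p = 0.824 with an estimated correlation), 8 of them adjusted over the list alone, with SAA1 differing by 3.90, CCL4 by 1.53 and CCL8 by 1.25. CCL4 was well above background on 1 of 2 P114 arrays. Antigen presentation genes (18 of 22, adjusted p = 0.000178), epithelial markers (12 of 17, adjusted p = 0.00237) and stem-like cell and sort markers (13 of 15, adjusted p = 0.0154) also had higher ratios, and 0, 2 and 0 of these passed adjusted over the list alone. These 3 lists had an adjusted p = 0.824 with an estimated correlation as well. In fits with no dye term the epithelial list lost its call without P114 replicate 1 (0.0731) or CMT-U27 replicate 1 (0.371), and the stem-like list without P114 replicate 1 (0.0706) or 2 (0.253). Of the antigen presentation genes with the smallest p for the difference, DLA-DRB1 and CIITA were well above background on 0 of 2 P114 arrays, and CD74 and DLA-DQB1 on 1 of 2. Cell cycle genes had lower ratios in 27 of 32 (median -0.14, adjusted p = 1.11e-09, and adjusted p = 0.824 with an estimated correlation), 0 of them adjusted over the list alone. With P114 replicate 1 turned, the cholesterol list had a median difference of 0.22 (adjusted p = 0.0745) and the cell cycle list pointed up (adjusted p = 0.716). With replicate 2 turned, the cholesterol list had a median difference of 0.17 (adjusted p = 0.184) and the cell cycle list an adjusted p of 0.974. The epithelial and stem-like lists lost the call with replicate 1 turned (0.0529 and 0.716) and pointed down with replicate 2 turned (both 0.894). Antigen presentation lost its call with median centring (0.124).

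Genes with a positive ratio in P114 and a negative one in CMT-U27 included COL12A1 (0.40 and -0.51), F3, the tissue factor gene (0.46 and -0.23), and HMGN2, a nucleosome-binding protein gene (0.32 and -0.25). The opposite held for CDKN1A, a cyclin-dependent kinase inhibitor gene (-0.39, negative by 2 of its 3 probes, and 0.19), and DDIT4, a stress-induced inhibitor of mTOR (-0.30 and 0.34). By its other probe DDIT4 stood at -0.05 and 0.05. Limma called 0 probes for the difference, with 821 at an unadjusted p under 0.05 (591 higher, 230 lower) and a smallest adjusted p of 0.264, for SAA1. Without background correction SAA1 passed as the 1 call, and with median centring 12448 passed. In fits with no dye term there were 61 calls without P114 replicate 2 and 8 without CMT-U27 replicate 1, and with P114 replicate 2 turned there were 20. Across probes the mean ratios of both lines correlated at a Pearson r of 0.131 and a Spearman rho of 0.182, and without P114 replicate 1, in a fit with no dye term, the Pearson r was -0.049. Probes are not independent replicates, so no p is given.

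**Figure D2:**
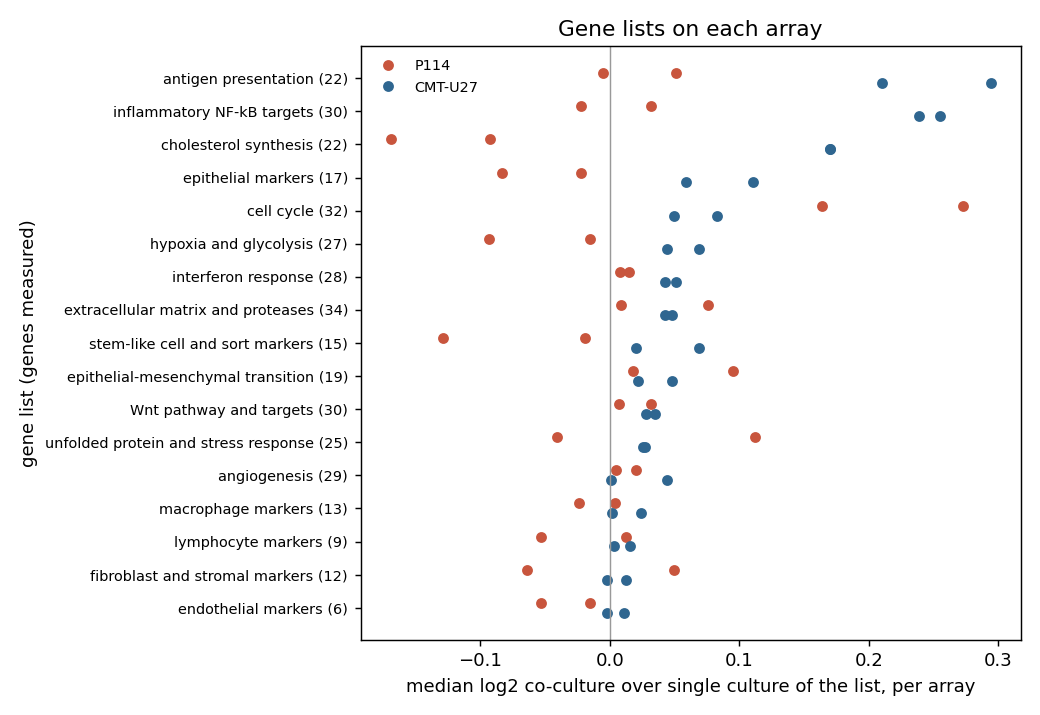
Median log2 ratio of co-culture over single culture (horizontal axis) of each gene list on each of the 4 arrays, with the number of genes measured in brackets. Cholesterol synthesis lies at 0.17 on both CMT-U27 arrays and at -0.09 and -0.17 on the P114 arrays, and inflammatory NF-kB targets at 0.24 and 0.26 on the CMT-U27 arrays and at 0.03 and -0.02 on the P114 arrays.

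Markers of the sort and of other cell types, were named whatever their values. EPCAM stood at -0.06 ± 0.09 in P114 and -0.11 ± 0.00 in CMT-U27, and CD44 at 0.00 ± 0.49 and 0.05 ± 0.01. VEGFA, the vascular growth factor gene, stood at 0.05 ± 0.15 and -0.12 ± 0.06, and by its other probe at 0.15 ± 0.05 and 0.04 ± 0.05. IL8 had opposite signs on the P114 arrays (-0.37 and 0.50) and stood at 0.58 ± 0.04 in CMT-U27. By its other probes IL8 stood lower in CMT-U27, between 0.10 and 0.30. CD163, a macrophage scavenger receptor gene, was not well above background in CMT-U27 (0 of 2 arrays in either culture) and stood at -0.02 ± 0.01 in P114. CSF1R was well above background in 2 of 8 channels and was not tested.

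In single culture the lines themselves differed at many genes. Limma's separate-channel fit called 4348 of 28692 probes, 2044 higher in P114 and 2304 higher in CMT-U27, and 2516 of them differed over 2-fold. Of 17 epithelial markers 11 were higher in CMT-U27 and 1 in P114, with EPCAM 6.18-fold higher in CMT-U27 (adjusted p = 0.000877). Of 19 genes of epithelial-mesenchymal transition 11 were higher in P114 and 2 in CMT-U27, and FN1, S100A4 and CDH2, the N-cadherin gene, had log2 differences of P114 minus CMT-U27 of 5.63, 6.19 and 4.83. Of 34 extracellular matrix and protease genes 16 were higher in P114 and 3 in CMT-U27, and of 27 hypoxia and glycolysis genes 8 and 1. STC1 (5.48), CDKN1A (4.24) and IL8 (3.69) were higher in P114, and CCL2 (-4.57) in CMT-U27. Antigen presentation genes (6 of 22), cell cycle genes (6 of 32) and 9 of 30 inflammatory NF-kB targets were higher in CMT-U27, against 0, 0 and 5 in P114. The lines lay on different arrays, and without CMT-U27 replicate 1 or 2 the count was 278 or 261.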

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

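Of the tests in this part, those of the dye label and of the probe chosen for each gene were written down before their result was seen, and all others were chosen after it. The test of culture differences was brought back, and the reading of the dye label test changed, after their values were seen. In 6 gene lists the co-culture effect differed between the lines by the test of the difference itself, with camera adjusted p-values of 2.16e-11 for cholesterol synthesis, 3.35e-10 for inflammatory NF-kB targets, 1.11e-09 for cell cycle, 0.000178 for antigen presentation, 0.00237 for epithelial markers and 0.0154 for stem-like cell and sort markers. All had an adjusted p = 0.824 with an estimated correlation.

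The 2 P114 arrays correlated at -0.149 once turned to co-culture over single culture. The dye bias that both lines share is argued against, since its median share in CMT-U27 was 0.087 of the P114 size, and so is locally bright background, since the correlation without such spots was -0.198. A wrong dye label on a P114 array could account for it, and so could P114 cultures that differed in a way unrelated to co-culture, and these cannot be told apart. The arrays also differed in ways that a wrong label alone would not produce. Spots well above background were 89.4% in Cy3 and 91.7% in Cy5 on replicate 1, against 61.5% and 60.4% on replicate 2. Before loess the median log2 ratio of the brightest spots was 0.84 against 0.01. Whether these differences bear on the correlation was not tested. Different probes of a gene correlated at 0.318 for the component that mirrors the labels, which met the bound set beforehand against a wrong label, but they correlated at 0.307 for the component that keeps its sign (0.088 in CMT-U27), and a wrong label only exchanges the roles of these components, so that bound was wrong. As labelled, replicate 1 correlated with the CMT-U27 arrays at 0.135 and 0.141 and replicate 2 at 0.105 and -0.137. For the mean of both lines, turning replicate 2 gave more probes at an unadjusted limma p under 0.05 with no dye term (3291 against 1723). With the dye term it gave fewer (1458 against 1881). These values leave open whether and on which array a label is wrong, and a line-specific response stays open as untested.

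Inflammatory genes were higher in co-cultured CMT-U27 cells. A single array as the source is argued against, since the list's median was above 0 on both arrays, the lower at 0.239. Carried-over macrophage RNA may contribute and cannot be excluded: the macrophage markers above background had a median log2 ratio of 0.046 against 0.259 for the inflammatory list, but only 8 of 31 markers were above background, among them CD14, CD68 and TLR2, and C1QC, FCER1G and SPI1 were so on 1 of 2 co-culture and 0 of 2 single-culture channels. A response of the tumour cells to co-culture stays among the open explanations.

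Cholesterol synthesis genes moved in opposite directions in the lines. A single array is argued against, since the medians had the line's sign on all 4 arrays, the smallest at an absolute value of 0.092, and so is the probe chosen for each gene, since with the mean over all probes the adjusted p of the difference was 5.20e-11. With P114 replicate 1 or 2 turned the call of the difference ended (adjusted p of 0.0745 and 0.184) with a smaller mean shift, 0.18 and 0.16 against 0.32, and a median of 0.22 and 0.17 against 0.25. The P114 median was -0.04 and 0.04 against -0.13, so a wrong label could account for the opposite direction in P114 but leaves a difference between the lines that did not pass. The turned fits took the dye term from the CMT-U27 arrays alone. A line-specific response to co-culture is a hypothesis that these arrays leave open.

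For the mean of both lines, all 8 assignments of directions to the arrays, in fits with no dye term, gave as many limma calls as the labelled one, which gave 0, and the highest of the others was also 0. At an unadjusted p under 0.05 the labelled one gave 1723 probes and the highest other 3291. So few assignments cannot give a share under 0.05.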

How the results depend on the processing

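Chosen after seeing the data were leaving out spots with a marked local background, a line's own arrays alone, and turning P114 replicate 1 or 2; all other alternatives were set before the data were examined. Each ratio already compared both cultures within an array. Across arrays, no paired analysis was possible because the labels give no replicate numbers. Values for lists are camera adjusted p-values, and the cause of a change was not tested unless stated. Signal over background left out 18 of 32 macrophage markers, 6 of 18 lymphocyte markers, 9 of 43 Wnt genes, 9 of 40 angiogenesis genes and 7 of 37 interferon response genes. It also limits the P114 values of CCL4, CCL20, CD74 and DLA-DQB1, above background there on 1 of 2 arrays, and of DLA-DRB1 and CIITA, on 0 of 2. No list that passed differed in sign between median, mean and test, and 23 of the 51 that did not pass differed.

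Without background correction, 12 probes passed in CMT-U27 and 1 for the difference. Lists newly past the threshold were antigen presentation and extracellular matrix in P114 (both 0.0476), epithelial markers (0.0133) and interferon response (0.000256) in CMT-U27, and interferon response in the mean (0.0133). With the scanner software's own log ratio, and equally with the series value table, epithelial (0.173) and stem-like markers (0.0971) in P114, extracellular matrix in the mean (0.146) and stem-like markers for the difference (0.146) lost the call, and interferon response gained it in CMT-U27 (0.000275) and the mean (0.023).

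With median centring in place of loess, which leaves in the trend with brightness, 5 probes passed in P114 (5 higher, 0 lower), 17343 in CMT-U27 (17025, 318), 16518 in the mean (16287, 231) and 12448 for the difference (12339, 109), and the correlation between lines was 0.741. In P114, macrophage (0.0331) and lymphocyte markers (0.00561) gained a call, and epithelial markers (0.376), stem-like markers (0.161) and cholesterol synthesis (0.348) lost it. In CMT-U27, calls were gained by macrophage (0.0032), lymphocyte (0.00149), fibroblast (0.0423) and epithelial markers (0.047), cell cycle (0.000116) and hypoxia (0.0032), lost by inflammatory targets (0.0542) and antigen presentation (0.397), and the stress response reversed (0.0214). In the mean, macrophage (0.00444) and lymphocyte markers (0.000899) gained, inflammatory targets (0.385), antigen presentation (0.722) and extracellular matrix (0.968) lost, and hypoxia (0.0106) and stress response (0.0251) reversed. For the difference, lymphocyte (0.00573) and fibroblast markers (0.0163), epithelial-mesenchymal transition (0.00679), angiogenesis (0.0181) and hypoxia (0.00236) gained, antigen presentation lost (0.124), and macrophage markers (0.00841), cell cycle (0.0377) and stress response (0.027) reversed.

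Without a filter on dim probes, epithelial and stem-like markers in P114 (both 0.0554) and extracellular matrix in the mean (0.0522) lost the call. With all channels above background, 1 probe passed in CMT-U27, antigen presentation (0.00169) and hypoxia (0.0348) in P114, stem-like markers in the mean (0.035) and angiogenesis for the difference (0.016) gained, and stem-like markers for the difference lost (0.114). Extracellular matrix in the mean lost its call with no dye term (0.0621) and with the mean over all probes (0.0679), where antigen presentation in P114 (0.0257) and angiogenesis for the difference (0.034) gained. With an estimated inter-gene correlation every called list lost its call, at 0.811 in P114, 0.94 in CMT-U27, 0.808 in the mean and 0.824 for the difference, a test that rests on 1 residual degree of freedom.

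Leaving out each array in turn, in fits that also dropped the dye term and with the lone array of a line assumed to vary like the others, gave 0 to 64 calls in P114, 0 to 17 in CMT-U27, 0 to 61 in the mean and 0 to 61 for the difference, and a correlation from -0.049 to 0.189. List values ran from 0.0239 to 0.343 for epithelial and from 0.00329 to 0.373 for stem-like markers in P114, from 0.00122 to 0.755 for epithelial markers in CMT-U27, and in the mean from 0.0158 to 0.906 for hypoxia and from 0.0315 to 0.331 for extracellular matrix. For the difference they ran from 5.83e-07 to 0.371 for epithelial markers, 0.00805 to 0.253 for stem-like markers, 0.00216 to 0.99 for hypoxia and 0.0148 to 0.723 for stress response. The line comparison ran from 261 to 4490 probes.

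Without spots of marked local background, hypoxia gained in P114 (0.0117) and for the difference (0.0354), stem-like markers gained in the mean (0.0431) and extracellular matrix lost (0.0759). Each turn left the dye term to the CMT-U27 arrays alone, so it entered the P114 values. With P114 replicate 1 turned, 14 probes passed in P114, 27 in CMT-U27 and 20 in the mean. In P114, epithelial (0.426), stem-like (0.885) and cholesterol lists (0.91) lost the call and cell cycle reversed (0.91), and in the mean cell cycle and extracellular matrix reversed (both 0.974). For the difference, epithelial (0.0529), stem-like (0.716) and cholesterol lists (0.0745) lost, cell cycle reversed (0.716) and stress response gained (0.0191). With P114 replicate 2 turned, which mirrors the P114 values of the other turn, 14 probes passed in P114, 27 in CMT-U27 and 20 for the difference, and the correlation was -0.031. In P114, epithelial (0.426), stem-like (0.885) and cholesterol lists (0.91) reversed and cell cycle lost (0.91). In the mean, cell cycle (0.716) and extracellular matrix (0.21) lost and stress response gained (0.0191). For the difference, epithelial and stem-like lists reversed (both 0.894), and cell cycle (0.974) and cholesterol synthesis (0.184) lost. The 18 settings were not all separate checks, so counts of settings passed overstate robustness. Aquantile left all ratios as in the main fit, and the series value table repeated the scanner software's own log ratio. Turning or leaving out a P114 array left the CMT-U27 ratios unchanged. Across the 18 settings, cell cycle in P114 passed in 15, at 5.15e-13 to 0.91, and inflammatory targets (2.29e-33 to 0.94) and antigen presentation (1.60e-22 to 0.94) in CMT-U27 in 16 each. Cholesterol synthesis passed in 14 in P114 (2.03e-06 to 0.91), in 17 in CMT-U27 (1.53e-08 to 0.94) and in 15 for the difference (1.80e-12 to 0.824). Epithelial markers in 9 in P114 (0.00426 to 0.811) and 13 for the difference (5.83e-07 to 0.894), stem-like markers in 9 in P114 (0.00329 to 0.885) and 10 for the difference (0.00239 to 0.894), and extracellular matrix in the mean in 5 (0.011 to 0.974). In the mean, inflammatory targets (9.10e-16 to 0.808), antigen presentation (8.94e-14 to 0.808) passed in 16 each and cell cycle (6.56e-10 to 0.974) in 15. For the difference, inflammatory targets passed in 17 (9.47e-19 to 0.824), antigen presentation in 16 (3.95e-08 to 0.824) and cell cycle in 14 (6.32e-10 to 0.974). Of 576 values of named genes, 525 had the same sign without background correction, 504 with the scanner software's own log ratio, 406 with median centring, 446 with P114 replicate 1 turned and 394 with replicate 2 turned.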

Other observations

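The test of macrophage RNA repeated here was chosen after the result was seen. In P114 the urokinase gene PLAU stood at 0.69 ± 0.06 and its receptor gene PLAUR at 0.46 ± 0.01, neither past the test, and were set side by side after their values were seen. In CMT-U27 they stood at 0.03 ± 0.10 and 0.02 ± 0.07. The differences of CMT-U27 minus P114 were -0.66 and -0.44, neither past the threshold. The plasminogen activator gene PLAT had positive ratios on all 4 arrays. Of the macrophage markers, 0 of 31 were well above background in both co-culture channels of CMT-U27 and in neither single-culture channel, CYBB was so in 2 co-culture channels and 1 single-culture channel, and the highest log2 ratio among those above background was 0.20, for TLR2, beside the median of 0.046.

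Named genes with opposite signs on the P114 arrays included S100A4, at -0.82 and 0.14, MXI1, at 0.47 and -0.46, and IL8. Probes beyond 0.5 in absolute log2 ratio on both arrays of a line were opposite in sign in 67 cases in P114, beside 7 higher and 16 lower on both. In CMT-U27 they were opposite in 12 cases, beside 27 higher and 0 lower on both.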
